A study of Mus musculus with 32 samples.

How the data were processed

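RNA was measured in 32 samples, 2 for each of 8 sorted populations of T cell development in mouse thymus and in artificial thymic organoids. Per the labels' protocols, populations were sorted by flow cytometry on surface markers, and libraries were made with a stranded total RNA kit for low input and sequenced with paired-end reads. The submitters' processing notes name STAR and the builds GRCm38 and GRCh38, with no version and no role for either build. How FPKM was computed, which annotation was used and whether the 2 samples of a group were averaged or pooled are not given in the sources used here.

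The authors deposited a single table of FPKM values (fragments scaled to transcript length and sequencing depth) with 2505 genes and 16 columns, 1 per group, with 2 decimals, per the file headers. No column of another group was present. The table is a selection of genes whose criterion is not given in the sources used here: 2499 are protein-coding in GENCODE M21, each reaches at least 3.12 FPKM in some column, and the lowest ratio of largest to smallest FPKM + 1 is 2.62. Rows lie in 26 runs, each ordered along the genome, of 3 to 255 genes. Counts of genes, gene list tests, correlations between columns and shares of variance are therefore relative to a set of genes that already vary. Housekeeping, ribosomal and stromal genes are largely not analysed here. Of all values, 5.31% are listed at 0. Gene names were matched to GENCODE M21 on GRCm38, where 2504 were found and 4 had more than 1 entry, and coordinates are from there. Whether low values moved in steps of 1 read was checked against 20 shuffled gene lengths; 11 of 16 columns did not exceed the shuffled scores, whole reads were not recovered and depth is unknown. Near-identical neighbours such as Hspa1a and Hspa1b, Akr1c12 and Akr1c13, and the H2-Q genes are uncertain where reads could be shared.

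The analysis had been planned on values per library. With 1 value per group, tests of the origin within a population, of the interaction, and of differences between origins in a step could not be fitted and are given as values, chosen by size. Values were analysed as log2(FPKM + 1) for 2458 genes with at least 1 FPKM in at least 2 columns. Averaged origin effects and steps were tested with limma 3.58.1 in R 4.3.3 (population plus origin, empirical Bayes with a mean trend, Benjamini-Hochberg adjustment over genes, threshold 0.05). This leaves 7 residual degrees of freedom, and the residual holds the variation of the origin difference between populations, with library error inside it. It is not a replicate error. Labels do not say whether the samples come from separate animals or cultures. On simulated data of 2458 genes with 200 changed genes, the origin test recovered 56.5% of log2 changes of 1 and 99.5% of changes of 2, with at most 4.8% false calls, and the DPearly to DPlate step test recovered 0% and 54.5%. The other steps were not simulated.

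Before the data were examined, 39 gene lists were fixed, of which 27 had at least 5 tested members. They were tested with camera (preset correlation 0.01) on the limma fit; of 64 list calls over the 9 contrasts, 1 held with an estimated correlation, and fry called 19. Camera compares a list with the other genes here, so its direction can differ from the sign of a list's median. Within a population, a list's median difference is given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins. Populations were compared between origins by Pearson's r across genes with an exact permutation of population names, and steps by Pearson's r and Spearman's rho across genes, without a p-value because genes are not replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

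Genes were named by a rule fixed before the data were examined: for the averaged origin effect the 10 largest in each direction past the test with the same direction in all populations, and up to 20 list members by adjusted p; for each population the 4 largest in each direction and 6 list members; for each step the 5 largest in each direction and 10 list members; for step differences the 4 largest; and the sorting antigens. Size replaced the adjusted p where no test was possible. Other list members named as examples, and genes of a described group, were chosen after their values were seen. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median centring and limma array weights. Leaving out each population in turn, leaving out ETP and DN2 together, and the counts of genes changed at least 2-fold in both origins were added after the data were seen. Within a population, 2-fold counts then took the place of the planned tests.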

Results

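The series compared developing mouse T cells made in artificial thymic organoids with the same sorted populations taken from the thymus. In an artificial thymic organoid, bone marrow stem and progenitor cells are aggregated with MS5 stromal cells that express the Notch ligand DLL4, and T cells develop in the aggregate. RNA was measured in 8 sorted populations that follow the order of T cell development: early T lineage progenitors (ETP), double negative 2 (DN2), double negative 3 (DN3), immature CD8 single positive (ISP8), early and late double positive (DPearly and DPlate), CD8 single positive (CD8SP) and CD4 single positive (CD4SP) cells. Each population was sorted from both origins, with 2 samples in each of the 16 groups and 32 samples in all. The deposited table holds 2505 genes and 1 FPKM value per group, so no value below has a replicate error and no difference within a single population has a replicate check. Total FPKM over the listed genes ran from 37251 in thymus DPlate to 55724 in organoid ETP. Read depth behind the values is unknown. Across the 2458 genes tested, the median organoid minus thymus difference of log2(FPKM + 1) was -0.0041 in ETP, 0 in DN2, 0.12 in DN3, 0.07 in ISP8 and in DPearly, 0.17 in DPlate, 0.26 in CD8SP and 0.37 in CD4SP. Values below are not adjusted for these shifts, and the percentile beside a list median compares it with random lists from the same columns. It ranks the median only, because genes of a real list vary together and those of a random list do not.

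The genes of the surface proteins used for sorting followed the population names in both origins. Kit, the stem cell factor receptor, stood at 83.02 FPKM in thymus ETP and 76.11 in organoid ETP, and at 32.4 and 41.04 in DN2. Cd44 was 62.14 FPKM in thymus ETP and 37.08 in organoid ETP, against 0.24 and 0.13 in DN3. Cd8a, a CD8 co-receptor chain, was 140.9 FPKM in thymus ISP8 and 154.88 in organoid ISP8, and Cd8b1, the other chain, was 245.78 and 267.82. Cd4 was 462.6 FPKM in thymus DPearly, 284.74 in organoid DPearly, 303.84 in thymus CD4SP and 117.84 in organoid CD4SP, and lay at 0.72 and 1.63 in CD8SP. The CD3 chain genes Cd3d, Cd3e and Cd3g were below 2 FPKM in ETP of both origins, and Cd3e reached 169.33 FPKM in thymus DN3 and 126.52 in organoid DN3. Sell, which encodes CD62L, was 138.68 FPKM in thymus CD8SP and 167.54 in organoid CD8SP. Il2ra, which encodes CD25, departed from this pattern: it was 350.33 FPKM in thymus DN3 and 1.53 in thymus ISP8, while organoid values were 459.83 in DN3, 61.89 in ISP8, 96.2 in DPlate and 40.48 in CD4SP.

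To ask whether each organoid population resembled its thymus counterpart, expression was correlated across the 2458 genes. On this scale organoid ISP8 and DPearly had the highest Pearson's r with their counterparts, 0.941 and 0.934, followed by DN3 at 0.893, DN2 at 0.879, CD8SP at 0.843, DPlate at 0.827, CD4SP at 0.799 and ETP at 0.788. In 6 of the 8 organoid populations the best match in thymus had the same name. Organoid DPlate matched thymus DPearly best, at r = 0.889, and organoid CD4SP matched thymus CD8SP best, at r = 0.838. The mean r of same-named populations was 0.863 against 0.586 for differently named ones. An exact permutation of the 8 thymus names gave a one-sided p of 2.48e-05, the smallest that these permutations can give. Genes are not independent replicates, so each r describes a pair of columns. Of the total sum of squares over genes, population took 80.4%, origin 6.92%, and their interaction together with library error 12.7%. These shares, the r values and the matching by name hold for a selected set of genes that all vary over the columns. A selection of genes by their change between populations would raise the population share, and the criterion is not given.

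**Figure D1:**
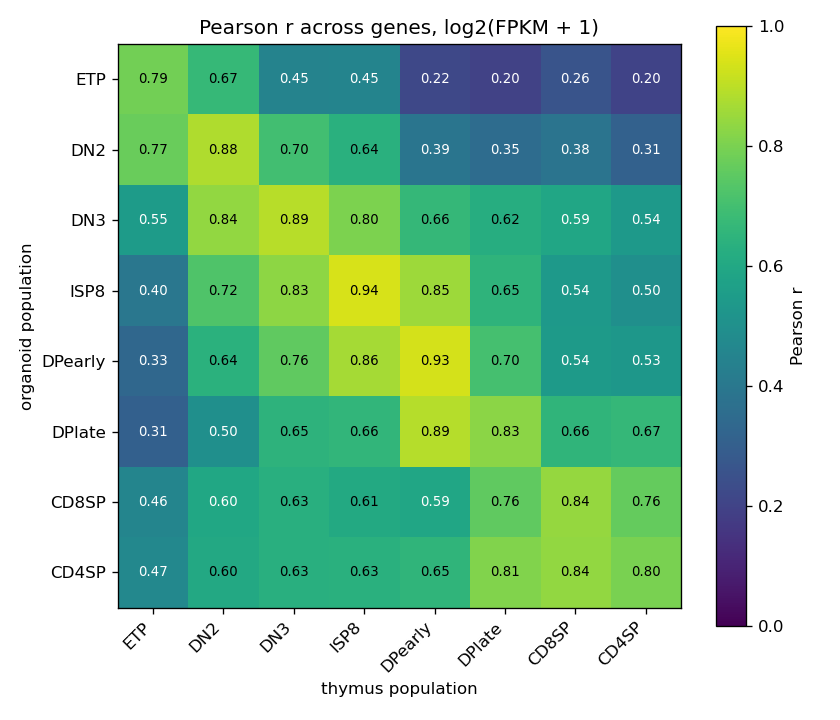
Pearson's r across 2458 genes between each organoid population (rows) and each thymus population (columns), on log2(FPKM + 1) with 1 deposited value per group. The diagonal runs from 0.79 in ETP to 0.94 in ISP8, and the DPlate row is highest under thymus DPearly at 0.89.

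Genes that differed between origins over the whole series were found from the 8 paired differences, 1 per population. The largest rise in the organoid among the genes called was in Gzmb, which encodes the cytotoxic protease granzyme B, with a mean log2 difference of 3.79 ± 0.70 (SE; adjusted p = 0.0132) and higher values in 7 of 8 populations. Gzma, which encodes granzyme A, rose by 3.32 ± 0.71 (adjusted p = 0.0247) and was higher in 6 of 8 populations. Il2ra rose by 2.91 ± 0.66 (adjusted p = 0.0296), higher in 7 of 8 populations, and the Notch target Dtx1 by 2.21 ± 0.51 (adjusted p = 0.0296), also higher in 7 of 8. Pmaip1, which encodes the pro-apoptotic protein NOXA (chromosome 18, 66458533 to 66465565), was higher in 8 of 8 populations, 4.74-fold on average for FPKM + 1 (log2 2.25 ± 0.24, adjusted p = 9.183e-04). The genes that rose most among those higher in every population were Khdc1a (log2 2.58), C3 of the complement system (2.50), Akr1c12 (2.30), the metallothionein Mt1 (2.29), Pmaip1, the interferon-induced Ifitm3, Casp1 (2.06), the fatty acid desaturase Fads2 (2.03), Cst7 (1.95) and Hp (1.94). Those that fell in every population were led by Gprc5b (log2 -1.88 ± 0.27, adjusted p = 0.00349; chromosome 7, 118972047 to 118995211) and Gpr174 (-1.67 ± 0.25, adjusted p = 0.00422; chromosome X, 107255878 to 107296769), followed by the kinase Sik1 (-1.40), the cholesterol exporter Abca1 (-1.38), Zfp827 (-1.37), Zfp831 (-1.34), Rapgef4 (-1.27), Rab11fip4 (-1.25), Lrig1 (-1.18) and Nfkbid (-1.16).

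Genes of cholesterol synthesis formed the most uniform group: all 8 members present in the deposited table rose, and 8 also passed when adjusted over the list alone. The list was fixed with 24 entries, and those absent from the selected genes could not be tested. Idi1 rose by log2 1.33 ± 0.22 (adjusted p = 0.00698), Mvd by 1.19, Cyp51 by 1.30, Sqle by 1.30, Insig1 by 1.17 and Dhcr24 by 1.18. The list passed camera (adjusted p = 8.303e-06) but not with an estimated correlation (adjusted p = 0.134 with an estimated correlation). Glycolysis and hypoxia genes passed camera (adjusted p = 0.0331), with 3 of 9 members up, among them Vegfa (1.50 ± 0.21, adjusted p = 0.00349) and Egln3 (1.35 ± 0.26), and 4 when adjusted over the list alone. All 24 proliferation genes had a positive mean, 1 rose over all genes tested and 20 when adjusted over the list alone, and the list passed camera (adjusted p = 8.303e-06). Myeloid (adjusted p = 0.0208) and NK and innate lymphoid genes (adjusted p = 0.0331) passed upward with 1 of 14 and 3 of 13 members up, 1 and 4 when adjusted over the list alone. The NK and innate members were Gzmb, Gzma and Fcer1g, and 11 of its 13 genes also stand in another list. Immediate early and heat shock genes passed downward (adjusted p = 5.438e-05) with 15 of 16 means negative and no member past the test over all genes or over the list alone. TCR stimulation and positive selection genes passed downward (adjusted p = 5.438e-05) with 2 of 23 down, 3 when adjusted over the list alone, including Dusp6 (-1.21 ± 0.25, adjusted p = 0.0206). TCR signalling components and interferon response genes also passed downward, both at an adjusted p of 0.0113, with 0 of 16 and 0 of 22 members down over all genes and over the list alone, and 1 interferon gene, Gbp3, up at 0.93. The interferon response median was not lower in every population: it was 0.89 in DN3, 0.59 in DPearly and 0.36 in ISP8. In the other populations it was negative, from -0.10 in DN2 to -1.50 in CD4SP. The 8 calls other than cholesterol synthesis were lost with an estimated correlation too, at an adjusted p of 0.816 for interferon response and 0.708 for each of the others. The TCR signalling call was also lost after quantile normalization (adjusted p = 0.124).

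In all, limma called 143 genes higher and 34 lower in the organoid, 177 of 2458, with 713 at an unadjusted p under 0.05. The error of this test is the variation of the origin difference between populations, and populations sorted from the same animals or cultures would not be independent, so the p-values measure how uniform a difference was over populations. Scaling changed the balance: 70 higher and 66 lower after quantile normalization, and 66 higher and 105 lower after centring each column on its median. Of the 177 genes, 103 were also called after quantile normalization and 100 after median centring. Centring overshot the shift between columns. It turned the median difference over genes negative from ISP8 on, to -0.34 in CD8SP and -0.42 in CD4SP. Without DPlate or without CD8SP only 33 genes passed, 41 without CD4SP, 46 without DPearly, 67 without DN3 and 89 without ISP8. In 133 genes the organoid value was higher in all 8 populations and in 43 lower.

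**Figure D2:**
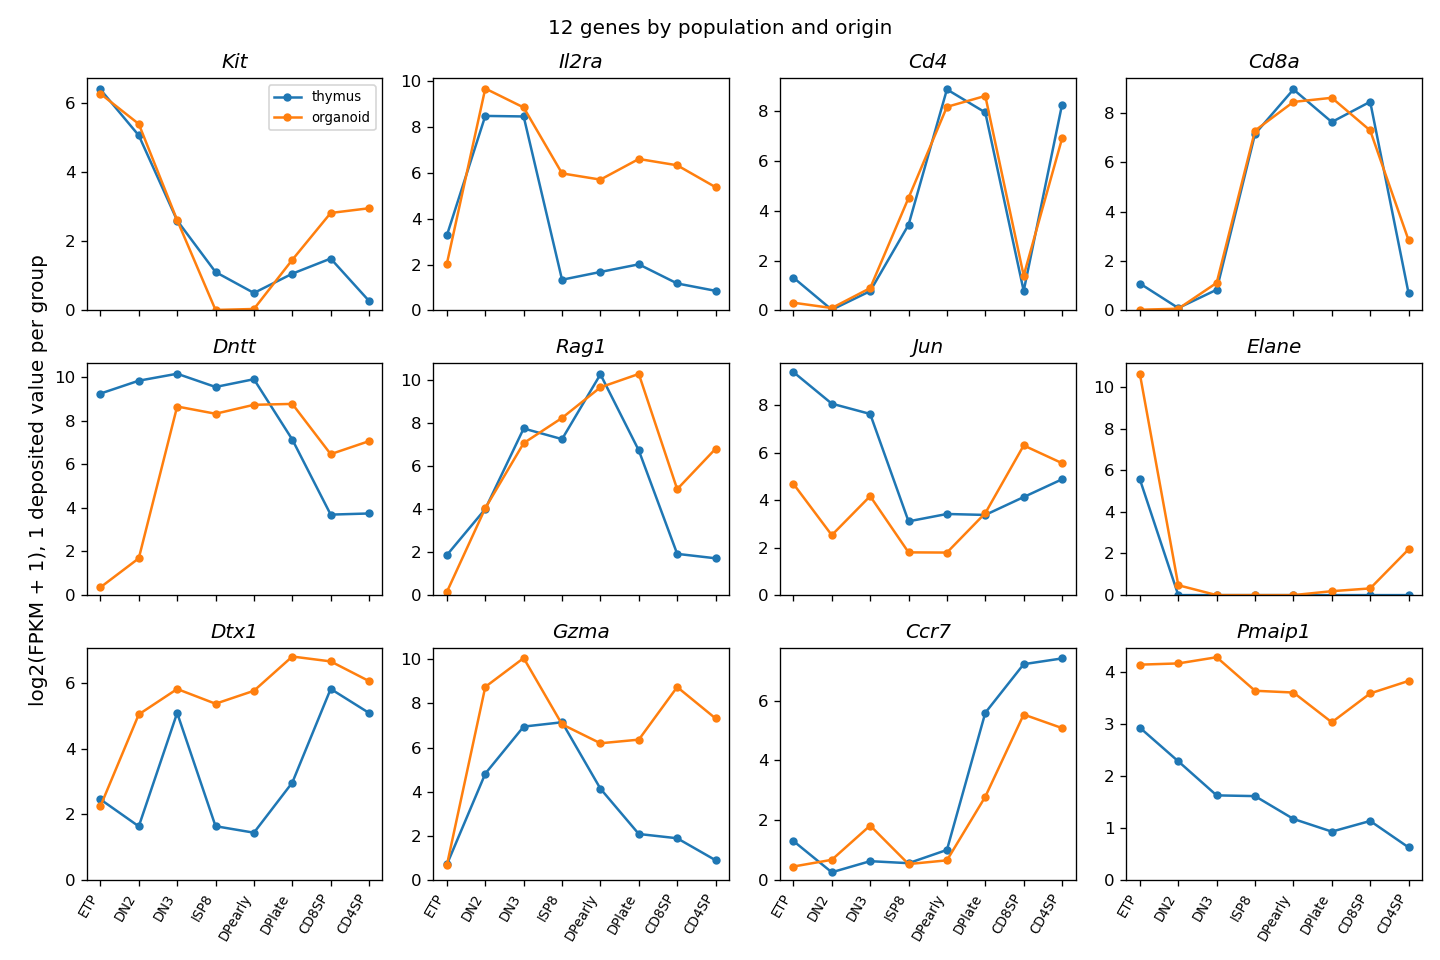
Log2(FPKM + 1) of 12 genes over the 8 populations in thymus (blue) and organoid (orange), with 1 deposited value per point and no error. Pmaip1 lies higher in the organoid in all 8 populations, while Dntt lies far lower in organoid ETP and DN2 and higher in organoid CD8SP and CD4SP.

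Within single populations the differences are described by size, as at least 2-fold on FPKM + 1. In ETP, 337 genes were higher and 421 lower in the organoid. Organoid ETP carried high levels of neutrophil granule genes: Elane stood at 1567.44 FPKM against 46.08 in thymus, Mpo at 2690.48 against 306.75, Prtn3 at 365.89 against 10.33 and Ctsg at 534.54 against 21.43. C3 was 86.8 FPKM against 0.62, and the myeloid receptor gene Igsf6 was also among the 4 largest, 5.14 higher on the log2 scale. Of 14 myeloid genes 10 were higher, with a median log2 difference of 2.93 (percentile 100 among random lists). Mast cell and basophil genes had a median of 2.14 (percentile 99.3), led by Gata2 at 85.57 FPKM against 4.35 and Hdc at 30.34 against 0.49. Dntt, which encodes terminal transferase, was 602.27 FPKM in thymus ETP and 0.28 in organoid ETP. Immediate early and heat shock genes were lower in 14 of 16 cases with a median of -2.43: Jun was 667.96 FPKM in thymus and 24.68 in the organoid, Hspa1b 131.51 and 0.57, and Hspa1a 62.28 and 0.12. The chemokine gene Ccl4 was 5.06 lower on the log2 scale. Notch targets (median -1.24), interferon response genes (-1.22), T lineage commitment genes (-0.93) and stem and progenitor regulators (-0.58) had negative medians too, at percentiles 0.4, 0.01, 1.82 and 0.29. The stem and progenitor regulators were split, with 9 of 23 at least 2-fold lower and 6 at least 2-fold higher.

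In DN2, 251 genes were higher and 240 lower in the organoid. Dntt was again the largest difference, 907.51 FPKM in thymus against 2.22 in the organoid. Immediate early and heat shock genes were lower in 13 of 16 cases (median -2.33, percentile 0), among them Jun at 265.29 against 4.75 FPKM, Fos at 41.07 against 0.72 and Hspa1b at 46.06 against 0.4. TCR signalling components had a median of -1.14 and T lineage commitment genes of -0.89, at percentiles 0 and 0.06. Gzmb was 221.25 FPKM in the organoid and 2.27 in thymus. B4galnt2, Ifitm1 and Fam20a were higher by 4.74, 4.48 and 4.47 on the log2 scale. Cytokine STAT5 target genes had a median of 0.59 (percentile 99.9) and Il2ra was 816.17 FPKM in the organoid against 356.1.

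In DN3, 324 genes were higher and 144 lower in the organoid. The adhesion receptor gene Cd2 stood at 135.85 FPKM against 1.88 in thymus, and Gzma at 1066.47 against 122.7. Gzmb, at 32.11 FPKM in the organoid, was listed at 0 in thymus. Gimap4 and Adam19 were higher by 4.91 and 4.93 on the log2 scale. T cell maturation and egress genes were at least 2-fold higher in 13 of 27 cases (median 0.90, percentile 100) and interferon response genes in 10 of 22 (median 0.89, percentile 99.96). NK and innate lymphoid genes were at least 2-fold higher in 6 of 13 cases and lower in 0 (median 0.56, percentile 98.1). Immediate early and heat shock genes were again lower, in 9 of 16 cases with a median of -1.35, including Fosb at 0.48 FPKM against 21.18 and Hspa1b at 1.04 against 39.37. Fam163b had the largest negative difference, -4.85. Recombination genes had a median of -0.63 (percentile 0.17), with Ptcra, which encodes the pre-TCR alpha chain, at 65.61 FPKM in the organoid and 169.46 in thymus.

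In ISP8, 227 genes were higher and 83 lower in the organoid. MHC class II genes had a median of -3.09 (percentile 0): Cd74 was 2.11 FPKM in the organoid and 44.36 in thymus, H2-Ab1 1.6 and 28.17, H2-Eb1 0.7 and 14.74, and H2-Aa 0.09 and 8.25. Dendritic cell genes had a median of -0.37 (percentile 1.31), with 1 of 6 at least 2-fold lower and 0 higher. Higher in the organoid were Il2ra at 61.89 FPKM against 1.53, Dtx1 at 40.58 against 2.11, and Socs3 and Stk39 by 3.27 and 3.05 on the log2 scale. Notch targets had a median of 0.93 (percentile 99.8).

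In DPearly, 216 genes were higher and 118 lower in the organoid. Notch targets had a median of 1.18 (percentile 100), with Dtx1 at 53.7 FPKM against 1.71, Il2ra at 51.12 against 2.2 and Notch3 at 42.56 against 10.02. Akr1c13 and Pdlim4 were higher by 2.69 and 2.62 on the log2 scale. The largest negative differences were in Tdrd5 (-3.91), Smoc1 (-3.81), Eya2 (-3.70) and the cystine transporter gene Slc7a11, at 0.59 FPKM against 17.08. Double positive stage genes had a median of -0.36 (percentile 0.1), with the chemokine receptor gene Ccr9 at 20.2 FPKM against 103.81. Cholesterol synthesis genes had a median of 1.40, glycolysis and hypoxia genes of 1.27 and proliferation genes of 0.86, at percentiles 100, 100 and 99.99.

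In DPlate, 544 genes were higher and 305 lower in the organoid. Genes of recombination and of the double positive stage were higher: Rag1, which encodes a recombinase subunit, was 1229.91 FPKM in the organoid and 104.17 in thymus, Ptcra 108.24 and 1.65, Rorc 258.35 and 33.08, and Dntt 433.57 and 139.03. All 7 recombination genes and 10 of 16 double positive stage genes were at least 2-fold higher, with medians of 2.52 and 1.47 (percentiles 100 and 99.9). Proliferation genes were at least 2-fold higher in 19 of 24 cases (median 1.60, percentile 100) and NK and innate lymphoid genes in 7 of 13 (median 1.08, percentile 99.8). TCR stimulation and positive selection genes were at least 2-fold lower in 12 of 23 cases (median -1.08, percentile 0): Itm2a was 18.42 FPKM against 398.8, Nab2 19.07 against 120.9 and Egr2 5.78 against 33.88. Cd5, at 105.39 FPKM against 203.36, fell just short of 2-fold. The lower median of this list was not particular to DPlate. It was -1.24 in ETP (13 of 23 genes lower, percentile 0), and -0.74 in DN2 and -0.50 in DPearly (percentile 0.02 for both). The list median was -0.02 in DN3 and -0.24 in CD8SP. In ISP8 and CD4SP it was 0.24 and 0.08, with a sign that changed under another scaling. Maturation and egress genes were lower in 10 of 27 cases (median -0.72, percentile 0.02), with Ccr7, a receptor for migration into the medulla, at 5.88 FPKM against 47.26. The macrophage lysozyme gene Lyz2 was 33.42 FPKM against 0.25, and myeloid genes had a median of 1.20 (percentile 99.99). Tle6 was higher by 4.57, and Eng, Zcchc12 and Itgb3 were lower by values of -3.32, -3.26 and -3.25 on the log2 scale.

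In CD8SP, 594 genes were higher and 179 lower in the organoid. Cd163l1 was 217.97 FPKM against 0.05, Gzma 428.04 against 2.69, the chemokine gene Ccl5 248.97 against 2.52, Gzmb 75.96 against 0.89 and the chemokine receptor gene Cxcr3 20.34 against 0.66. NK and innate lymphoid genes had a median of 1.42 (percentile 99.8). Endou was 90.78 FPKM against 0.5 and Ptcra 13.28 against 0.09, and 6 of 7 recombination genes were at least 2-fold higher (percentile 99.8 for the median). Proliferation genes were at least 2-fold higher in 22 of 24 cases (median 1.46). Lower in the organoid were Tmie at 0.46 FPKM against 36.31, Apol9b, Eng and Rarg by values of -3.81, -3.60 and -3.45, and 8 of 22 interferon response genes (median -0.83, percentile 0). Cd8a itself was 155.23 FPKM against 348.86 and Ccr7 45.36 against 148.1.

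CD4SP showed the most differences, 767 genes higher and 206 lower. Genes of the CD8 lineage were at least 2-fold higher in 15 of 18 cases (median 2.83, percentile 100), including Gzmb at 127.85 FPKM against 0.08, Gzma at 158.96 against 0.85, Nkg7 at 65.48 against 0.47 and Eomes at 7.88 against 0.63. NK and innate lymphoid genes were at least 2-fold higher in 9 of 13 cases (median 2.68, percentile 100). Of the 18 CD8 lineage genes 9 also stand in another list, and Gzmb, Gzma and Eomes are in both of these. Cd8a was 6.19 FPKM against 0.62 and Cd8b1 63.31 against 18.64. Ccl5, at 27.85 FPKM in the organoid, was listed at 0 in thymus. Zbtb16, which encodes the innate-like T cell regulator PLZF, was 30.75 FPKM against 0.27. Genes of gamma delta and innate-like T cells, 1 list, had a median of 1.49 (percentile 99.1), against 0.97 in CD8SP (percentile 98.3). Regulatory T genes had a median of 2.21 (percentile 99.9). All 24 proliferation genes were at least 2-fold higher (median 2.52), and Rag1 was 109.85 FPKM against 2.27. Plac8 was higher by 5.16 on the log2 scale. Interferon response genes were lower in 17 of 22 cases (median -1.50, percentile 0). Tmie was 1.19 FPKM against 49.22, and Apol9b, Amigo2 and Spsb1 had differences of -3.64, -3.61 and -3.46. The differences between populations in these origin effects were not tested.

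**Figure D3:**
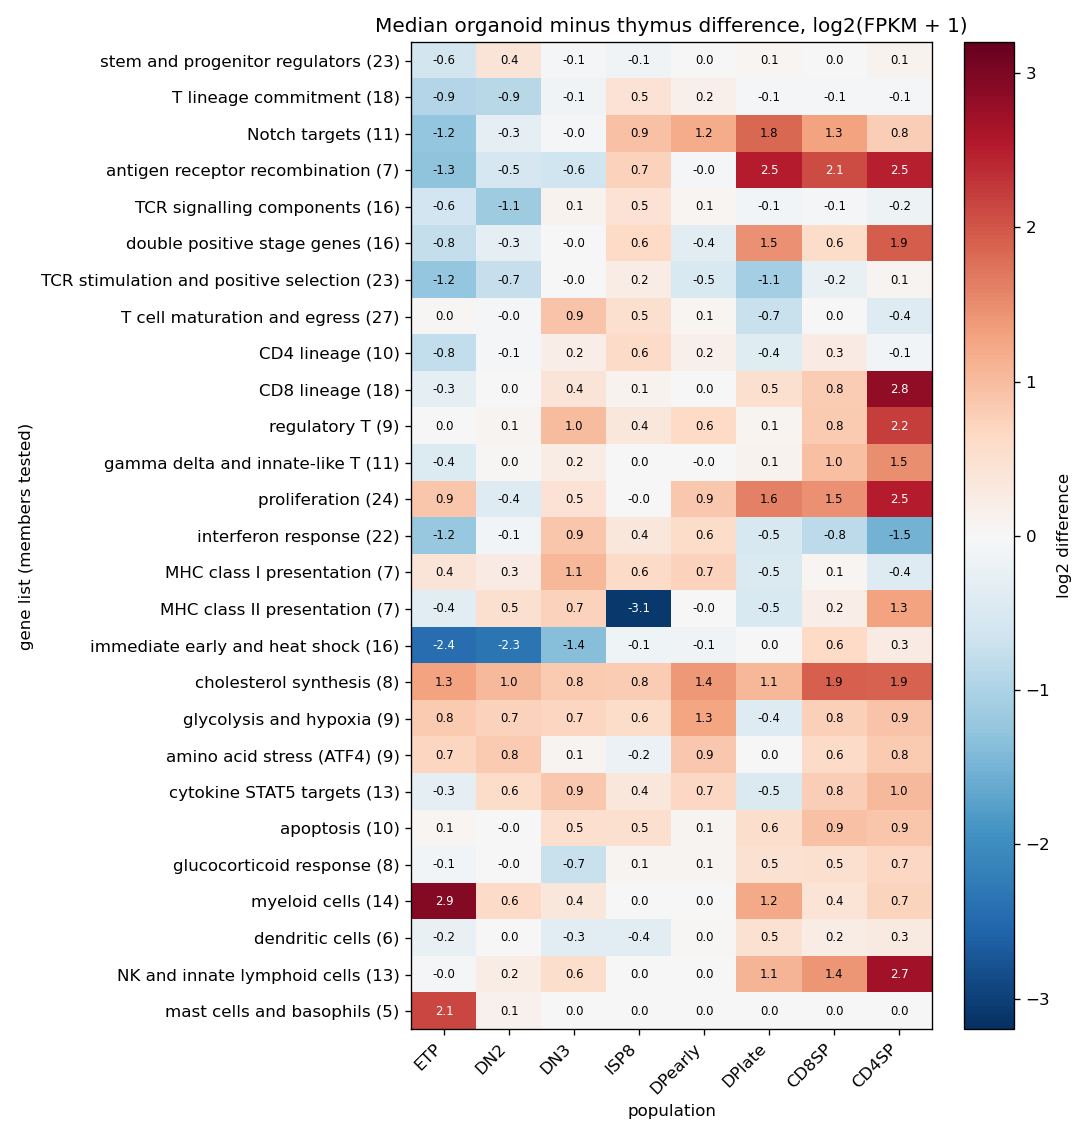
Median organoid minus thymus difference of log2(FPKM + 1) for each gene list with at least 5 members (rows, members in parentheses) in each population (columns), with 1 deposited value per group. Immediate early and heat shock genes lie at -2.43, -2.33 and -1.35 in ETP, DN2 and DN3, and cholesterol synthesis genes lie above 0 in all 8 populations; some medians near 0 change sign with the scaling.

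Development was then followed step by step, with each change averaged over thymus and organoid; every gene named as past a step's test changed the same way in both origins. From ETP to DN2, Cd3g rose by a mean log2 change of 6.15 ± 0.48 (SE; adjusted p = 1.692e-05), Cd3e by 4.90 ± 0.45, the commitment factor gene Bcl11b by 5.63 ± 0.55 (adjusted p = 8.361e-05), Il2ra by 6.42 ± 1.33, and Gzma, Mcub and Rasgrp1 by 6.10, 5.09 and 3.97. Falls were largest in Elane (-7.85 ± 0.99, adjusted p = 5.282e-04), Mpo (-5.86), Prtn3 (-5.62), the progenitor regulator Lmo2 (-4.67) and Igsf6 (-4.26), and included Flt3 (-4.24), Csf1r (-3.71), Meis1 (-3.14) and Cd34 (-2.95). Of 23 stem and progenitor regulators 13 fell, 17 when adjusted over the list alone, a call that held in camera with an estimated correlation (adjusted p = 0.0374 with an estimated correlation). TCR signalling components rose in 10 of 16 cases and T lineage commitment genes in 11 of 18, 11 and 12 when adjusted over the list alone, while 8 of 14 myeloid genes fell, 13 when adjusted over the list alone. These 3 list calls were lost with an estimated correlation (adjusted p = 0.134 for each). In all 53 genes rose and 132 fell, 119 in all when genes needed at least 5 FPKM. The split was 76 and 90 after quantile normalization and 89 and 74 after median centring. Thymus and organoid changes correlated across genes at r = 0.527 (rho 0.482), with 317 genes at least 2-fold changed one way in both. The largest untested differences between the origins' changes were in Lcn4, C3, B4galnt2 and Igsf6.

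From DN2 to DN3, Lef1 rose by 5.35 ± 0.65 (adjusted p = 5.756e-04), Cd3d by 5.15 ± 0.49 (adjusted p = 1.271e-04), Ptcra by 5.07 ± 1.31, H2-Q2 by 4.72, Arl5c by 4.18 and Id3 by 2.85. The haemoglobin gene Hbb-bt (-5.98 ± 0.51, adjusted p = 9.189e-05), Fgf3 (-5.31), the progenitor factor genes Hhex (-5.07), Lyl1 (-4.33) and Spi1 (-3.43), the mast cell protease gene Cpa3 (-4.60), Nrgn (-4.59), Cd34 (-2.99) and Nfe2 (-2.62) fell. Stem and progenitor regulators fell in 10 of 23 cases, 14 when adjusted over the list alone (adjusted p = 0.0659 with an estimated correlation). T lineage commitment genes rose in 6 of 18 cases and TCR signalling components in 5 of 16, 12 and 10 when adjusted over the list alone (adjusted p = 0.481 with an estimated correlation for each). In all 50 genes rose and 94 fell, against 84 and 81 after quantile normalization and 77 and 83 after median centring. The changes of the origins correlated at r = 0.687 (rho 0.627) and 348 genes changed at least 2-fold one way in both. Without ETP the model called 239 genes. Dntt, Klf2, Cd2 and Adam19 differed most between the origins' changes, without a test.

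From DN3 to ISP8, Cd8a rose by 6.24 ± 0.69 (adjusted p = 7.499e-04) and Cd8b1 by 5.23 ± 0.70, with Cd4 at 3.14, Ikzf3 at 2.71 and Gpr162 at 2.42. Scin (-5.52 ± 0.79, adjusted p = 0.00322), Khdc1a (-5.14), Nkg7 (-4.28), Atp8b4 (-4.24), Cdh1 (-4.09), Erg (-3.41), Epcam (-3.26), the Notch modifier Lfng (-3.13), H2-Q7 (-2.73), Sell (-2.68) and Nfe2 (-2.68) fell. Of 7 MHC class I presentation genes 4 fell, 6 when adjusted over the list alone, and all 24 proliferation genes had a positive mean with none past the test over all genes or over the list alone; both lists passed camera (adjusted p = 0.00131 and 4.828e-11) but not with an estimated correlation (adjusted p = 0.892 for both). In all 10 genes rose and 103 fell, and 72 passed without DPearly. Falls still outnumbered rises after quantile normalization, with 27 up and 39 down, while median centring turned the split to 157 up and 45 down. The origins' changes correlated at r = 0.682 (rho 0.659) with 437 genes at least 2-fold changed in both. Cd74, Gzmb, Ifitm1 and Il2ra differed most between origins, without a test.

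From ISP8 to DPearly, Cd4 rose by 4.54 ± 0.59 (adjusted p = 0.00993) and was the single gene called, while 516 genes stood at an unadjusted p under 0.05 in limma. The changes of the origins were nevertheless the most alike of any step, r = 0.854 (rho 0.821), and 227 genes changed at least 2-fold one way in both, 104 up and 123 down. Thymus changed more: 497 genes were at least 2-fold higher and 445 lower in thymus, against 108 and 135 in the organoid. Double positive stage genes passed camera upward (adjusted p = 9.626e-06) with 15 of 16 means positive. The list had 1 member up over all genes and 2 when adjusted over the list alone (adjusted p = 0.648 with an estimated correlation). The 1 member up over all genes is Cd4, a sorting antigen gene whose rise from ISP8 to DPearly the gates favour in advance. With array weights 426 genes were called. Cd74, Smoc1, H2-Ab1 and H2-Eb1 differed most between origins, without a test.

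From DPearly to DPlate, Gimap4 rose by 5.77 ± 1.19 (adjusted p = 0.0413), Gimap3 by 5.04 ± 0.81 (adjusted p = 0.0294), Ctss by 4.65, Cd7 by 3.97, Cd53 by 3.96, Slfn1 by 3.53, Ctsw by 3.51, the nuclear receptor gene Nr4a3 by 3.31 ± 0.51 (adjusted p = 0.0294), Egr2 by 3.24 ± 0.52, H2-Q7 by 3.11 and Lfng by 2.90. E2f8 (-2.89 ± 0.63), Rrm2 (-2.85), Pclaf (-2.70), Pbk (-2.55) and Cdca3 (-2.47) fell. TCR stimulation and positive selection genes rose in 7 of 23 cases, maturation and egress genes in 10 of 27 and MHC class I presentation genes in 5 of 7, and 13, 15 and 6 did when adjusted over the list alone (adjusted p = 0.212 with an estimated correlation for each). Proliferation genes fell in 3 of 24 cases, 24 when adjusted over the list alone (adjusted p = 0.362 with an estimated correlation). In all 44 genes rose and 42 fell, against 66 and 172 after quantile normalization and 57 and 196 after median centring. Without ETP, or without ISP8, limma called 0 genes, with 509 and 482 at an unadjusted p under 0.05. It called 9 without DN3, 3 without CD8SP, 168 without DN2 and 225 without CD4SP. The origins' changes correlated at r = 0.520 (rho 0.421), with 379 genes at least 2-fold changed in both and 35 in opposite directions. Itm2a, Smoc1, Slc7a11 and Tle6 differed most between origins, without a test.

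From DPlate to CD8SP, the egress receptor gene S1pr1 rose by 4.30 ± 0.67 (adjusted p = 0.00498), with Cst7 at 4.27, H2-Q6 at 4.01, Gvin1 at 3.82, Dapl1 at 3.81 ± 0.50 (adjusted p = 0.00238), Lfng at 3.57, Ms4a4b at 3.15, H2-Q7 at 2.99, Ms4a4c at 2.93, Ms4a6b at 2.57, Pim2 at 2.52 and Sell at 2.27. Cd4 fell by 7.18 on the log2 scale (SE 0.59, adjusted p = 5.781e-05), and Rag1 (-5.08 ± 1.32), Plxnd1 (-4.60), Rorc (-4.09) and F13a1 (-3.76) fell as well. Maturation and egress genes rose in 11 of 27 cases and CD8 lineage genes in 8 of 18, while 7 of 16 double positive stage genes fell, with 19, 11 and 10 when adjusted over the list alone (adjusted p = 0.552 with an estimated correlation for each). Among these 7 is the sorting antigen gene Cd4, whose fall the CD8SP gate favours in advance. In all 138 genes rose and 76 fell; after quantile normalization 100 rose and 138 fell, and after median centring 104 rose and 148 fell. The origins' changes correlated at r = 0.679 (rho 0.680) with 449 genes at least 2-fold changed in both. Il17rb, Cd163l1, Itm2a and S100a6 differed most between origins, without a test.

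From DPlate to CD4SP, S1pr1 rose by 4.47 ± 0.67 (adjusted p = 0.0155), Rflnb by 3.37, Lfng by 3.36, Ifi27l2a by 3.27, Dapl1 by 3.17, Slfn1 by 3.15, Ms4a4b by 2.98, Ms4a4c by 2.52 and Ms4a6b by 2.40. Cd8a (-6.35 ± 0.69, adjusted p = 0.00133), Cd8b1 (-3.83) and Aldh7a1 (-1.78) fell. Maturation and egress genes rose in 6 of 27 cases and double positive stage genes fell in 2 of 16, with 16 and 12 when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation for each). Among the genes called lower, Cd8a and Cd8b1 encode the antigen that the CD4SP gate excludes, which favours their fall in advance. The count of 2 over all genes therefore does not stand for the double positive stage as a whole. In all 26 genes rose and 3 fell; with a pseudocount of 0.1 the model called 1 gene, and it called 15 without DN2, 16 without DN3, 11 without ISP8 and 14 without DPearly. Quantile normalization gave 18 and 11, and median centring 15 and 8. The origins' changes correlated at r = 0.493 (rho 0.454), with 290 genes at least 2-fold changed in both. Nkg7, Ccr4, Nrgn and Adgrg5 differed most between origins, without a test.

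Between CD4SP and CD8SP, Cd8a was higher in CD8SP by 6.10 ± 0.69 (adjusted p = 0.00104) and Cd4 lower by a log2 difference of -6.48 ± 0.59 (adjusted p = 1.884e-04), and no other gene passed limma, with 94 at an unadjusted p under 0.05. All 18 CD8 lineage genes had a positive mean and the list passed camera (adjusted p = 8.153e-22), with 1 member, the sorting antigen gene Cd8a, past the test over all genes and 9 when adjusted over the list alone; adjusted p = 0.117 with an estimated correlation. The CD4 lineage list passed camera downward in CD8SP (adjusted p = 4.034e-06) with 1 of 10 members, the sorting antigen gene Cd4, past the test over all genes and when adjusted over the list alone, and adjusted p = 0.130 with an estimated correlation. The difference between these populations was the least alike in the origins, r = 0.363 (rho 0.247), with 57 genes at least 2-fold different one way in both. Within origins the 2 populations correlated at r = 0.921 in thymus and 0.954 in the organoid. Nkg7, Itgae, Cxcr6 and Eng differed most between origins, without a test: Nkg7 was 141.42 FPKM in thymus CD8SP and 0.47 in thymus CD4SP, against 174.87 and 65.48 in the organoid.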

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

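All tests of explanations in this part were chosen after the results were seen. For each of the 27 gene lists with at least 5 members, the 8 medians of the organoid minus thymus difference were searched for 1 population far from the other 7 (gap over range above Dixon's 95% critical value for 8 values); 6 lists had one, and chance gives about 1 in 20, or 1.35. The 8 populations are not samples of 1 group, so this only ranks them. CD8 lineage genes stood apart in CD4SP at 2.83, with CD8SP next at 0.81. Regulatory T genes stood apart in CD4SP at 2.21, with DN3 next at 1.02. MHC class II genes stood apart in ISP8 at -3.09, with DPlate next at -0.49. Glycolysis and hypoxia genes were lowest in DPlate at -0.42, with ISP8 next at 0.58. Mast cell and basophil genes were highest in ETP at 2.14, with DN2 next at 0.13.

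Myeloid genes stood apart in ETP at 2.93, with DPlate next at 1.20. Scaling does not account for it: the lower of the medians after quantile normalization and median centring was 2.94. Other c-Kit positive progenitors inside the organoid ETP gate may contribute, and would lower T lineage genes together with the myeloid rise. The T lineage commitment median in ETP came no nearer to 0 than -0.46 over the deposited scale and both scalings, which lies between the bounds set for and against this explanation, so progenitors of another type and a myeloid-leaning profile inside the T progenitors cannot be told apart from 1 pooled value per group. The gate removes lineage-positive cells but not c-Kit positive granulocyte or mast cell precursors.

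Immediate early and heat shock genes were lower in organoid ETP, DN2 and DN3. Scaling is argued against, since the median nearest to 0 over these 3 populations and both scalings was -1.45. Handling that raised these genes alike in all thymus samples was left undecided by the bound set for it, although values on the deposited scale go against an equal rise. The medians were -2.43, -2.33 and -1.35 in ETP, DN2 and DN3. In the 5 later populations, ISP8 to CD4SP, they were -0.13, -0.10, 0.02, 0.64 and 0.26 on the deposited scale. In CD8SP 7 of the 16 genes were at least 2-fold higher in the organoid and 1 lower. The bound set against this explanation was missed by -0.54 in CD4SP after median centring, so a smaller shared part stays open. Handling of the early thymus populations alone could give the pattern, with 8 of the 16 genes at least 2-fold lower in all 3 early populations, as could a difference inside the tissue, and the design does not separate them.

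Recombination genes were higher in organoid DPlate, CD8SP and CD4SP. The lowest median over these 3 populations and both scalings was 1.50, which argues against scaling. Double positive cells with the Cd4 level of organoid DPlate are argued against as the whole source in the CD8SP gate. Cd4 there reached 0.422% of its organoid DPlate level, while the 7 recombination genes reached 2.38% (Rag1) to 54.9% (Xrcc6), with Rag2 at 4.79%. Cd4 in this gate, like the CD8 genes in the CD4SP gate, belongs to an antigen that the sort excludes, which by itself favours low values. Double positive cells low in that antigen are therefore not covered. In CD4SP the 7 genes reached 8.93% (Rag1) to 36.5%, with Rag2 at 10.0% and a median of 26.1%. Cd8a stood at 1.59%, or 17.8% of the lowest of them, and Cd8b1 at 8.28%. The Cd8a value argues against double positive cells with the Cd8a level of organoid DPlate as the whole source there. Double positive cells low in Cd8a cannot be excluded, since Cd8b1 lies near Rag1 and Rag2 and the values have no spread. A part from double positive cells cannot be told apart from transcripts kept by the single positive cells. In DPlate the recombination genes lay 76.1% (Rag2) to 178% (Dclre1c) of the way from thymus DPlate to organoid DPearly, with a median of 104%, while the 24 proliferation genes lay at most 28.0% of the way, which argues against cells like the organoid DPearly population as the whole source. Early cells that do not cycle may contribute, as may a less advanced population. A median of 31.9% of the way from organoid DPearly to thymus DPlate was reached by 17 positive selection genes. They were chosen as at least 2-fold higher in thymus DPlate than in thymus DPearly, with organoid DPearly below thymus DPlate. Thymus DPlate was thus both a basis of the choice and the end point. This favours a low share in advance, so the value decides nothing about either explanation.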

How the results depend on the processing

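Settings leaving out populations, and the counts of genes at least 2-fold changed in both origins with their alternatives, were chosen after the data were seen; 2-fold counts within a population then took the place of the planned tests, with the alternatives fixed before the data were examined. Of 1773 values of named genes under alternatives, none changed sign, 1508 kept their side of the threshold and 265 no longer passed. These genes were named for their size or adjusted p in the main fit, which favours kept signs in advance. The counts therefore say little about genes that were not named. Depth is unknown, so what it limits cannot be given. At the level of replicates, no paired analysis was possible because the deposited columns hold 1 value per group and carry no replicate numbers, and the averaged origin effect pairs the origins by population only; the replicate block, leaving out single libraries, and fits of single populations were not run for that reason. Same-population similarity kept its direction and passed under all settings (0.229 to 0.298 without single populations), and the shares of variance moved by less than 5 points. The cause of the changes below was not tested.

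The averaged origin effect called 280 genes with array weights, and 33 to 219 without single populations. Steps with array weights called 84 (ETP to DN2), 240 (DN2 to DN3), 333 (DN3 to ISP8), 426 (ISP8 to DPearly), 299 (DPearly to DPlate) and 9 (DPlate to CD4SP). With the filter of 5 FPKM, which tests fewer genes, ETP to DN2 called 119 and DPearly to DPlate 192. Quantile normalization gave 66 for DN3 to ISP8 and 238 for DPearly to DPlate, and median centring 202 and 253. A pseudocount of 0.1 gave 0 for ISP8 to DPearly, with 510 at an unadjusted p under 0.05 in limma, and 1 for DPlate to CD4SP. Without ETP and DN2, ISP8 to DPearly called 0, DPearly to DPlate 3 and DPlate to CD4SP 2. Without single populations the steps called 137 to 164, 105 to 239, 72 to 138, 1, 0 to 225, 171 to 232, 11 to 25 and 2 genes, in the order of the text.

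A pseudocount of 0.1 raised the genes at least 2-fold different between origins to 799 in DN2, 794 in DN3, 740 in ISP8 and 708 in DPearly, and those changed in both origins to 500, 591, 688, 423, 636, 695, 471 and 136 over the 8 steps. It moved the fold correlation to 0.608 for DN3 to ISP8, 0.748 for ISP8 to DPearly and 0.306 for CD4SP to CD8SP. For gene lists under the averaged origin effect, 9 passed camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 3 with fry.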

Other observations

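Gzma was 430.23 FPKM in organoid DN2 and 27.14 in thymus DN2, and Klrb1c, Klrd1 and Tbx21 stood at 9.9, 43.75 and 10.49 FPKM in organoid CD8SP against 0.13, 21.53 and 1.11 in thymus. Tyrobp, an abundant adaptor gene of NK and myeloid cells, was 1.67 FPKM in organoid CD8SP and 2.09 in organoid CD4SP. Itgae, which encodes an integrin of tissue-resident CD8 cells, was lower in organoid CD8SP at 37.37 FPKM against 191.38, and Prf1 was 8.34 against 20.03. Pdgfrb, the 1 stromal gene of 24 in the table, was higher in 7 of 8 organoid populations and lower in ETP, at 38.06 against 73.4 FPKM.

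The test of the hypothesis below was chosen after its values were seen. Notch target genes had medians of 0.93, 1.18, 1.85 and 1.29 in organoid ISP8, DPearly, DPlate and CD8SP, while they were lower in ETP at -1.24. In CD4SP the median of 0.79 changed sign under another scaling. A candidate explanation is continued exposure to the DLL4 ligand in the organoid; the lowest median over these 4 populations, the deposited scale and both scalings was 0.58. Transcripts kept from earlier stages were not tested as an alternative. Il2ra was 51.12 FPKM in organoid DPearly and 96.2 in organoid DPlate, and Dtx1 53.7 and 111.97, while Nrarp was 4.27 and 1.92. No group of the design lacks the ligand, so the explanation stays open.

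The averaged origin effect was also set against exchanges of thymus and organoid labels within populations. Of 100 such splits, 1, the real one, called as many as 177 genes, and the highest of the others called 0. An exchange also moves the origin difference into the residual, which lowers the counts of the other splits in advance. The populations may share animals or cultures as well. The rank of the real split therefore does not exclude chance as the source of this count.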
